A study of Mus musculus with 41 samples.

How the data were processed

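RNA-seq was carried out on MEEC, a wild-type mouse embryonic endocardial cell line, in 41 libraries that fall into 13 groups and 3 experiments. RNA was extracted with a PicoPure kit and libraries were made with the NEBNext Ultra kit, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, RSEM and limma, and the mouse genome build GRCm38, without versions. The trimming settings, the annotation release and the strand setting of the counting were not given in the sources used here.

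The authors deposited 1 table of normalized signal per gene for each experiment, with 13886, 12984 and 13407 genes. The deposited signal is scaled to a common library size: each value is a whole number of reads plus an offset of 0.5, divided by a scaled library size. The step between low values gives what 1 read is worth, and dividing by it returned whole reads for 100% of values in every library, within 0.01 reads. In 30 libraries the step was found from at least 100 low values, while 11 libraries held fewer low values and their step rests on less. A value expected from RSEM need not be whole, so the authors' signal appears to come from rounded estimates. The libraries held 14.1 to 16.8 M reads (M, mega) in the first experiment, 19.4 to 25.2 M in the second and 11.2 to 34.2 M in the third. The ratio of the authors' scaled library size to the sum of reads ran from 0.9562 to 1.044 in the first experiment, 0.9665 to 1.023 in the second and 0.97 to 1.022 in the third. A floor of 3 reads, the upper limit that a count of 0 allows at 95% confidence, corresponds to a signal of 0.179 to 0.221, 0.119 to 0.158 and 0.0859 to 0.266 in the 3 experiments. Such floors cover counting error only, since PCR copies are not independent molecules. The 10 most abundant genes held between 4.27% and 5.55% of the signal of a library.

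Genes are listed by Ensembl identifiers. Of these, 13863, 12964 and 13384 matched the mouse annotation of build GRCm38 used here, which gave symbols and positions, and 23, 20 and 23 did not. The first table also pairs 13660 identifiers with names, 99% of which equal the annotation's symbol. Reads of near-identical copies (pseudogenes, ribosomal protein genes, the paired beta-globin genes) and of overlapping genes cannot be assigned with certainty from these tables.

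Because the values are normalized and linear, log2(signal + 1) was fitted with limma 3.58.1 in R 4.3.3 (moderated statistics with a mean-variance trend), using all groups of a table in 1 fit and Benjamini-Hochberg adjustment over the genes of the table. Adjusted p values in the text come from this limma fit unless another tool is named, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(signal + 1) scale, which understates the change of genes with low signal. The minimum of 1 in as many libraries as the smallest group removed 0 genes, so every listed gene was tested. Each table was normalized separately, so tests stay within a table. The design, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, apart from those said to have been chosen later. The 18 contrasts were each ligand against its control, ligand against ligand, inhibitor against vehicle, ligand plus inhibitor against ligand alone and against vehicle, the control co-culture at 24 h against 6 h, and 3 interactions. The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold for each of the 15 pairwise contrasts: between 92% and 99% of the 2-fold changes and between 99% and 100% of the 4-fold changes were called, with 2% to 9.2% of calls false. The changed genes all had a mean signal of at least 4, and counts were drawn independently, without paired or outlying libraries. Recovery of weaker genes or smaller changes in the real libraries may be lower.

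Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Over 45 pairs of libraries of the same group, chi-square per gene lay between 5.52 and 52.63, so no pair agreed within sampling noise and each library counted once. Libraries carry replicate numbers in their titles. For every pairwise contrast within a time point or experiment, same-numbered libraries deviated together from their group means. Their correlations across genes were 0.16 or more in every pair (above the threshold of 0.1), so the numbers pair the samples. The main fit, fixed beforehand, leaves this pairing out, so its counts and the genes that did not pass depend on that choice. A fit with the number as a block was set beside the result where it moved it. In the first experiment that block gives each number 1 effect over both times, although, as given next, the numbers do not pair between times. For the control co-culture at 24 h against 6 h the correlations ran from 0.04 to 0.17, so there the numbers do not pair the samples. For the interactions the lowest were -0.01, 0.02 and -0.04, so not every pair deviated together. For inhibitor by ligand 17 of 18 pairs lay above the threshold.

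Genes named are, for each contrast of ligand or inhibitor, the 10 raised and 10 lowered genes of largest absolute log2 fold change with an adjusted p under 0.05, a mean of at least 2 on the log2 scale and groups that do not overlap (a non-overlap that chance gives in 10% of genes with 3 against 3), leaving out predicted genes. The number was 5 and 5 for ligand against ligand, ligand plus inhibitor against vehicle, the time contrast and interactions. Added to these were 9 fixed genes (Hey1, Hey2, Heyl, Hes1, Nrarp, Notch1, Notch3, Dll4 and Jag1, where measured) and up to 4 members of smallest adjusted p of each list described. Where fewer than 3 genes passed, the 3 of smallest p are named as not passing.

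The 27 gene lists cover Notch targets, Notch pathway components, arterial and tip cell genes, endothelial and endocardial identity, epithelial to mesenchymal transition, smooth muscle and contractile genes, BMP and TGF-beta signalling, endocardial secreted factors, extracellular matrix, Wnt signalling, DNA replication and S phase, mitosis and G2/M, p53 response, interferon response, NF-kB and inflammatory genes, immediate early genes, hypoxia and glycolysis, cholesterol biosynthesis, amino acid stress and unfolded protein response, oxidative phosphorylation, ribosomal proteins and heat shock. Lists of cells that the cultures could hold or of RNA quality cover OP9 stromal and adipogenic markers, leukocyte and erythroid markers, cardiomyocyte markers, epithelial markers and mitochondrially encoded transcripts. Lists with at least 5 measured members were tested with camera (preset correlation 0.01), adjusted over the lists of a contrast, and again with an estimated correlation, given as such beside the call. As an alternative, fry tested whether the genes of a list move 1 way on balance, without comparing them with other genes. Genes called in one experiment were also tested as lists (at most 100 genes) in libraries that played no part in choosing them, adjusted over 74 such tests.

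Alternatives tried were the replicate block, no filter and a stricter filter, a pseudocount of 0.25, quantile normalization, only the groups named in a contrast, no mean-variance trend, library weights, an absolute log2 fold change of at least 1, leaving out each library in turn, and edgeR 4.0.16 (quasi-likelihood) on the recovered reads. How MEEC RNA was kept apart from RNA of the OP9 feeder cells, how much recombinant ligand was attached to the wells, and whether RO4929097 stayed in the medium during the 6 h over OP9-GFP, was not given in the sources used here. The 24 h co-cultures were seeded at 25% confluency and the 6 h co-cultures at 50%, so time and density change together. Reads and alignments were not analysed here. A few genes that the naming rule picked are not reported here.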

Results

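Gene expression was measured by RNA-seq in MEEC, cells of an embryonic mouse line derived from the endocardium, the inner lining of the heart, after Notch signalling had been stimulated or blocked. In 18 libraries MEEC had been laid over OP9 stromal cells that carried GFP, the Notch ligand Dll4 or the Notch ligand Jag1, for 6 h or 24 h (n = 3 libraries per group). In 8 libraries MEEC had first spent 24 h in the vehicle DMSO or in 20 µM RO4929097, which blocks the gamma-secretase that releases the active Notch fragment, and then 6 h over OP9-GFP (n = 4). In 15 libraries MEEC had grown on wells coated with recombinant ligand (rDLL4 or rJAG1) or without it, with DMSO or RO4929097, for 38 h including 14 h without serum (n = 3). Libraries held a median of 15.2, 22.5 and 18.1 M reads in the 3 experiments. Group values are normalized signal as mean ± SD, and log2 fold changes are given ± SE.

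The first comparison asked what contact with Dll4 or Jag1 changed in MEEC after 6 h. Over OP9-Jag1, known Notch targets rose: Nrarp, a feedback inhibitor of the pathway, stood at 29.5 ± 10.6 against 7.57 ± 1.69 over OP9-GFP (log2 fold change 1.79 ± 0.30, adjusted p = 0.025). Hey1 stood at 5.98 ± 1.02 against 2.60 ± 0.63 (0.96 ± 0.17, adjusted p = 0.032) and Hey2 at 16.3 ± 2.19 against 8.72 ± 1.41 (0.84 ± 0.13, adjusted p = 0.02). Hey1 (chromosome 3, 8663359 to 8667256, minus strand) and Hey2 (chromosome 10, 30832359 to 30842801, minus strand) encode transcriptional repressors, as does Hes1 (chromosome 16, 30064384 to 30067796, plus strand). Tuft1 rose to 126.9 ± 2.50 from 71.4 ± 3.21 (0.82 ± 0.07, adjusted p = 3.9e-05). Edn1, which encodes the vasoconstrictor and growth factor endothelin-1 (chromosome 13, 42301476 to 42307990, plus strand), fell to 12.4 ± 1.90 from 22.0 ± 3.13 (-0.79 ± 0.12, adjusted p = 0.02). The growth factor gene Fgf5 and the insulin signalling adaptor gene Irs1 changed by -0.57 ± 0.10 (adjusted p = 0.043) and -0.48 ± 0.08 (adjusted p = 0.032). Hes1 stood at 61.5 ± 4.08 against 40.8 ± 4.68 (0.59 ± 0.11) with adjusted p = 0.055, or 2e-04 with the replicate number as a block.

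Of 8 measured Notch targets, 3 rose over OP9-Jag1 at 6 h (4 rose and 1 fell adjusted over the list alone), and the list rose in the camera test with adjusted p = 1.8e-08, or 0.0012 with an estimated correlation. Of 27 endocardial secreted factors, 1 fell (3 adjusted over the list alone), with list adjusted p = 0.26. In all, 10 genes were higher and 4 lower. With the replicate number as a block, 82 genes changed, and 467 with the numbers blocked within each time, an alternative chosen after seeing the data. Library weights gave 594, and fitting only the 2 groups named gave 1. Leaving out OP9-GFP library 1 left 1 gene, OP9-GFP library 3 left 3, and leaving out OP9-Jag1 libraries 1, 2 and 3 left 4, 3 and 1. At 6 h OP9-Jag1 library 2 stands apart from OP9-Jag1 libraries 1 and 3 (chi-square per gene of 21.61 and 12.93, against 6.36 between those). Tuft1 kept its call in 6 of the 6 fits that left out 1 library, Edn1 in 2, Nrarp, Hey1 and Hey2 in 1 each, and Fgf5 and Irs1 in 0.

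Over OP9-Dll4 at 6 h, 1 gene rose, Tuft1 (101.8 ± 5.70 against 71.4 ± 3.21, log2 fold change 0.51 ± 0.07, adjusted p = 0.034), which encodes an acidic enamel protein (chromosome 3, 94612757 to 94658872, minus strand). Aggf1, an angiogenic factor gene, did not pass (0.42 ± 0.08, adjusted p = 0.23, or 0.015 with the replicate number as a block). Neither did Nrarp (20.1 ± 9.36, 1.22 ± 0.30, adjusted p = 0.54, or 0.0041 with the block) and Hes1 (56.0 ± 5.57, 0.45 ± 0.11, adjusted p = 0.54, or 0.0081 with the block). As a list, the 8 Notch targets rose (adjusted p = 2.1e-05, or 0.0098 with an estimated correlation), with 0 called over all genes and 4 adjusted over the list alone. With the block 7 genes changed, and 162 with the block within each time (chosen after seeing the data). Library weights gave 113. The count of 1 went to 0 in each fit that left out 1 library except the fit without OP9-Dll4 library 2. That library stands apart from the 6 h OP9-Dll4 libraries 1 and 3 (chi-square per gene of 30.77 and 17.97, against 7.24 between those). Set against each other at 6 h, the ligands gave 0 genes with limma (258 at an unadjusted p under 0.05) and 0 with edgeR (255 at an unadjusted p under 0.05). Library weights gave 194 for this comparison, and fitting only these 2 groups gave 1. The Notch targets were lower over OP9-Dll4 as a list (adjusted p = 0.0035), with 0 members called over all genes and 0 adjusted over the list alone, and adjusted p = 0.085 with an estimated correlation.

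At 24 h, contact with OP9-Jag1 raised 144 genes and lowered 137. The largest increases among named genes were in Il33, which encodes an alarmin cytokine (186.1 ± 82.8 against 33.6 ± 16.8, log2 fold change 2.43 ± 0.38, adjusted p = 0.0033). Also among the largest were the basement membrane collagen genes Col15a1 (13.8 ± 2.34 against 1.73 ± 0.18, 2.43 ± 0.38, adjusted p = 0.0033) and Col18a1 (2.06 ± 0.24, adjusted p = 0.00041), and Nrarp (46.1 ± 10.4 against 8.75 ± 0.96, 2.25 ± 0.30, adjusted p = 0.00098). Hey1 rose to 9.86 ± 1.36 from 1.86 ± 0.25 (1.92 ± 0.17, adjusted p = 1e-05), Hey2 by 1.13 ± 0.13 (adjusted p = 0.00041) and Heyl, near the floor, by 1.02 ± 0.22 (adjusted p = 0.018). The receptor gene Notch1 rose by 0.83 ± 0.15 (adjusted p = 0.0057), and Jag1 itself by 0.61 ± 0.13 (65.6 ± 3.38 against 42.8 ± 3.31, adjusted p = 0.019). Dsg2, a desmosomal cadherin gene, the imprinted noncoding RNA gene H19 and Emilin2, an elastic fibre glycoprotein gene, rose by 1.89 ± 0.33, 2.00 ± 0.42 and 1.69 ± 0.26. Edn1 fell to 15.8 ± 0.78 from 33.6 ± 1.83 (-1.04 ± 0.12, adjusted p = 0.00041). Fbln5, an elastic fibre gene on chromosome 12 (101746565 to 101819055, minus strand), fell to 99 ± 12.3 from 179 ± 2.16 (-0.86 ± 0.07, adjusted p = 5.5e-06), and the hyaluronan-degrading gene Cemip changed by -0.99.

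Grouped by list, 4 of 8 Notch targets rose over OP9-Jag1 at 24 h (6 rose and 1 fell adjusted over the list alone, list adjusted p = 4.4e-09, or 0.00065 with an estimated correlation). Of 25 genes of epithelial to mesenchymal transition, 4 rose (7 rose and 1 fell adjusted over the list alone), among them the FGF receptor gene Fgfr1 (0.59 ± 0.10), the repressor gene Zeb2 (0.47 ± 0.09) and the hyaluronan synthase gene Has2 (0.92 ± 0.19). That list had adjusted p = 1e-05, and adjusted p = 0.11 with an estimated correlation. The p53 response had 3 of 20 members raised (7 raised and 1 lowered adjusted over the list alone), including the cell cycle inhibitor gene Cdkn1a (0.83 ± 0.18), with adjusted p = 2.3e-05 and adjusted p = 0.11 with an estimated correlation. Extracellular matrix genes went both ways, 3 up and 2 down of 35 (6 and 2 adjusted over the list alone, adjusted p = 0.031, and adjusted p = 0.91 with an estimated correlation). Of the endocardial secreted factors 5 rose, Tgfb2 among them (0.65 ± 0.10, adjusted p = 0.0033), and 3 fell (7 and 5 adjusted over the list alone), with list adjusted p = 0.62. The endothelial progenitor marker Cd34 and the flow-responsive factor gene Klf4 fell, by 0.59 ± 0.07 and 0.42 ± 0.08, as 2 of 18 endothelial and endocardial identity genes (2 adjusted over the list alone, adjusted p = 0.12). Of 23 Notch pathway components 1 rose (Notch1) and 2 fell (the same counts adjusted over the list alone, adjusted p = 0.34). Those that fell were Rbpj, which encodes the DNA-binding partner of the active Notch fragment (-0.25 ± 0.06), and Psen2, a gamma-secretase subunit gene (-0.65 ± 0.12). Arterial and tip cell genes had 0 of 6 called (3 raised adjusted over the list alone, adjusted p = 0.18). Wnt signalling genes had 0 of 15 called (0 adjusted over the list alone, adjusted p = 0.99) and OP9 stromal markers 0 of 13 (0 adjusted over the list alone, adjusted p = 0.74).

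The count of 281 over OP9-Jag1 at 24 h became 628 with the replicate number as a block, and 1512 with the block within each time (chosen after seeing the data). It became 166, 121 and 114 without OP9-GFP library 1, OP9-GFP library 2 and OP9-Jag1 library 1, and 136 without OP9-Jag1 library 3. Il33, Col15a1, Nrarp, Hey1, Hey2, Notch1, Edn1 and Fbln5 kept their calls in all 6 fits that left out 1 library, whereas Zeb2 kept its call in 4, Heyl, Has2 and Klf4 in 3, Cdkn1a and H19 in 2, and Jag1 and Rbpj in 1.

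**Figure D1:**
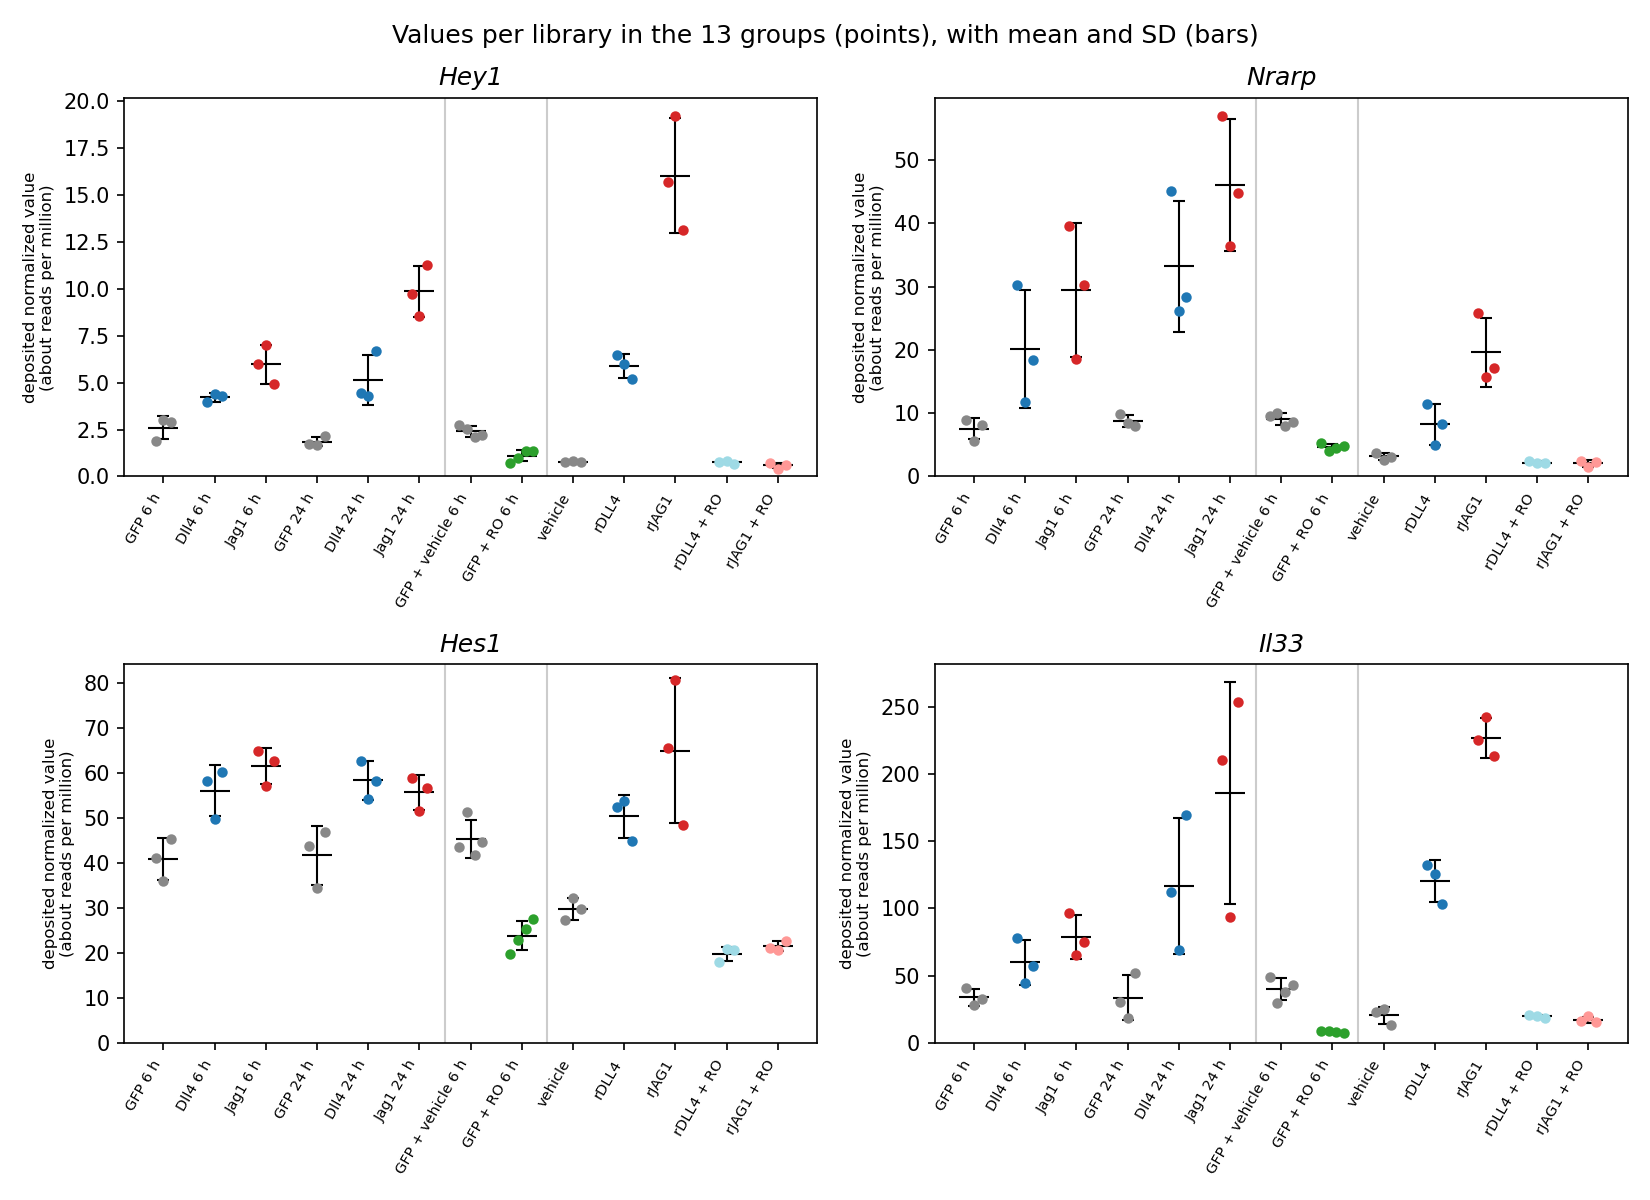
Normalized signal of Hey1, Nrarp, Hes1 and Il33 in each of the 41 libraries, by group, with the mean and SD. Each experiment was normalized separately, so levels are comparable within an experiment only. In the third experiment Hey1 stood at 16 ± 3.05 on rJAG1 and 0.586 ± 0.151 on rJAG1 with RO4929097.

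OP9-Dll4 at 24 h raised 37 genes and lowered 34, among them Il33 (116.9 ± 50.5, log2 fold change 1.79 ± 0.38, adjusted p = 0.049), Nrarp (33.2 ± 10.3, 1.77 ± 0.30, adjusted p = 0.014) and Col18a1 (38.0 ± 5.39 against 12.7 ± 3.59, 1.54 ± 0.24, adjusted p = 0.0076). Hey1 rose to 5.15 ± 1.34 (1.09 ± 0.17, adjusted p = 0.0072) and Hey2 to 18.9 ± 2.08 from 9.99 ± 1.16 (0.86 ± 0.13, adjusted p = 0.0076). Fbln5 fell to 108.4 ± 2.77 (-0.72 ± 0.07, adjusted p = 7.4e-05). Edn1 fell to 20.9 ± 1.45 (-0.66 ± 0.12, adjusted p = 0.02) and Cd34 to 46.3 ± 4.09 from 64.9 ± 5.59 (-0.48 ± 0.07, adjusted p = 0.0072). Of 8 Notch targets 3 rose (4 rose and 1 fell adjusted over the list alone, list adjusted p = 6e-07, or 0.0026 with an estimated correlation). Genes of epithelial to mesenchymal transition had 0 of 25 called (4 raised adjusted over the list alone, adjusted p = 2.5e-05, and adjusted p = 0.15 with an estimated correlation). NF-kB and inflammatory genes had 1 of 27 raised (2 adjusted over the list alone, adjusted p = 9.3e-05, and adjusted p = 0.4 with an estimated correlation).

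The OP9-Dll4 libraries also held transcripts of heart muscle and blood, named here after their values were seen. At 24 h, 4 of 10 cardiomyocyte markers rose (4 adjusted over the list alone, adjusted p = 6e-07, or 0.022 with an estimated correlation). They were the cardiac myosin genes Myh7 (chromosome 14, 54970684 to 54994626; adjusted p = 0.0072) and Myl2 (chromosome 5, 122100951 to 122113472; adjusted p = 0.0013), the cardiac actin gene Actc1 (adjusted p = 0.0058) and the titin gene Ttn (adjusted p = 0.015). All genes listed for the first experiment reached a signal of 1 in as many libraries as the smallest group. These 4 did so only through OP9-Dll4 libraries, so their place in the list depended on the tested group. The list p values were thus partly set in advance and count as no support. The adjusted p values of the 4 genes were favoured in the same way. Myh7 had 265, 96 and 98 reads in the 24 h OP9-Dll4 libraries and 0, 2 and 86 in those of 6 h. It had at most 2 in the 12 libraries without Dll4. Myl2 had 58, 28 and 28 reads at 24 h against 0 in libraries without Dll4. The beta-globin gene Hbb-bs, which shares reads with its near-identical copy, had 75, 16 and 27 reads (adjusted p = 0.018), against at most 1 in the co-cultures without Dll4. Hbb-bs too was listed for the first experiment only through OP9-Dll4 libraries, which favoured its adjusted p. In the third experiment, where MEEC grew without OP9 cells, every library held it, with 5 to 34 reads (21, 11 and 6 in vehicle). Over all experiments, the presence of Hbb-bs is therefore not particular to the OP9-Dll4 libraries. Among the co-cultures alone it stood out only in the OP9-Dll4 libraries with Myh7 above those without Dll4, with 0, 0 and 16 reads at 6 h. Of 19 leukocyte and erythroid markers 3 were measured, too few to test as a list.

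**Figure D2:**
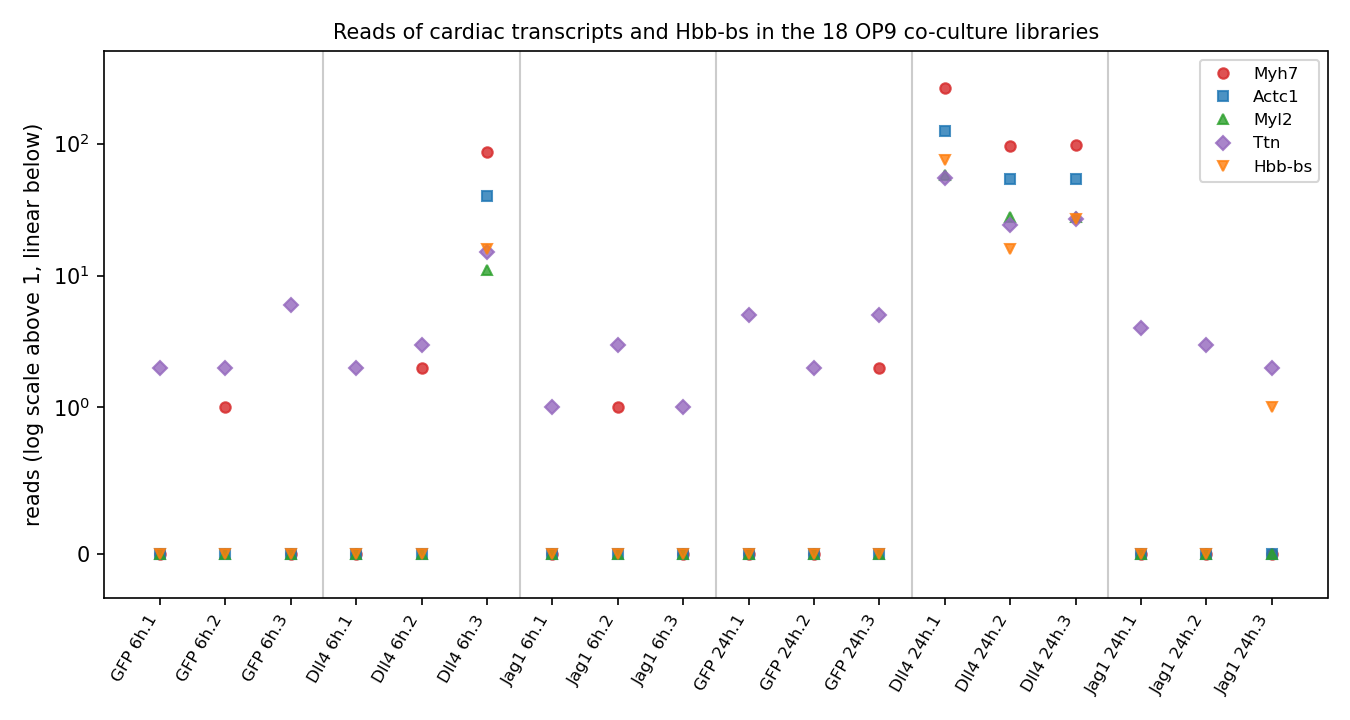
Reads of Myh7, Actc1, Myl2, Ttn and Hbb-bs in each of the 18 co-culture libraries, on a symmetric log axis. Myh7 reaches 265 reads in an OP9-Dll4 library at 24 h and 86 in 1 of the 3 OP9-Dll4 libraries at 6 h, and at most 2 in libraries without Dll4.

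With the replicate number as a block, 247 genes changed over OP9-Dll4 at 24 h, and 808 with the block within each time (chosen after seeing the data). After quantile normalization 31 rose and 18 fell. The count of 71 became 29, 18 and 13 without OP9-GFP libraries 1, 2 and 3, and 10 and 18 without OP9-Dll4 libraries 1 and 3. Hey1, Fbln5, Cd34, Myl2 and Actc1 kept their calls in all 6 such fits, Myh7 in 5, Hey2 in 4, Nrarp, Col18a1 and Ttn in 3, and Il33, Edn1 and Hbb-bs in 1. Without the cardiac and erythroid transcripts, an alternative chosen after seeing the data, 45 genes changed, and edgeR called 46. The extracellular matrix list, called with adjusted p = 0.027 (1 of 35 raised and 1 lowered, 3 and 2 adjusted over the list alone, and adjusted p = 0.87 with an estimated correlation), had adjusted p = 0.099 after quantile normalization.

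Directly compared at 24 h, OP9-Dll4 exceeded OP9-Jag1 in 4 genes, Myl2 (adjusted p = 0.0053), Actc1 (adjusted p = 0.02), Myh7 (adjusted p = 0.02) and Ttn (log2 difference 1.45 ± 0.23, adjusted p = 0.036), and 0 genes were lower. All 4 are cardiomyocyte markers (4 of 10, 5 adjusted over the list alone, adjusted p = 3.1e-20, or 0.00036 with an estimated correlation). These 4 reached a signal of 1 only in OP9-Dll4 libraries, so their being listed depended on the tested group. The list p values therefore count as no support, and the adjusted p values of the 4 genes were favoured in the same way. Hey1 stood at 5.15 ± 1.34 over OP9-Dll4 and 9.86 ± 1.36 over OP9-Jag1, a difference of -0.83 ± 0.17 that did not pass (adjusted p = 0.27). The Notch targets were lower over OP9-Dll4 as a list (adjusted p = 4.1e-05, or 0.007 with an estimated correlation), with 0 of 8 called (2 lower adjusted over the list alone). With the block 7 genes differed, with the block within each time (chosen after seeing the data) 67, and with edgeR 0 (267 genes had an unadjusted p under 0.05 with limma). Leaving out OP9-Dll4 library 1 or 3 left 1 or 7 genes, and OP9-Jag1 libraries 1, 2 and 3 left 0, 1 and 1. Myl2 kept its call in 5 of these 6 fits and the other 3 genes in 2.

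The control co-cultures over OP9-GFP differed between 24 h and 6 h in many genes, 1312 higher and 1348 lower at 24 h, where both the time and the seeding density (25% against 50%) differed. Cholesterol biosynthesis genes rose at 24 h, 13 of 25 (15 adjusted over the list alone), among them the HMG-CoA synthase gene Hmgcs1 (231.9 ± 38.9 against 109.4 ± 3.11, log2 fold change 1.06 ± 0.13, adjusted p = 9.3e-05). Of 30 genes of amino acid stress and unfolded protein response, 10 rose and 1 fell (13 and 1 adjusted over the list alone), including the endoplasmic reticulum chaperone gene Hspa5 (0.86 ± 0.13). These lists had adjusted p = 1e-07 and 0.00097, and adjusted p = 0.97 with an estimated correlation for both. Fgfr1 fell to 16.7 ± 1.3 from 50.8 ± 2.85 (-1.56 ± 0.10, adjusted p = 4e-07). The cytoskeletal gene Gas7 changed by -3.13 ± 0.27, the collagenase gene Mmp13 by -2.63 ± 0.41 and the flow-responsive factor gene Klf2 by -0.78 ± 0.10. The Notch targets Hey1 (-0.32, adjusted p = 0.18), Hes1 (0.02, adjusted p = 0.9) and Nrarp (0.20, adjusted p = 0.67) did not pass.

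Other lists of that comparison were as follows. The p53 response had 7 of 20 raised (8 adjusted over the list alone, adjusted p = 0.00028, and adjusted p = 0.51 with an estimated correlation). Ribosomal protein genes, whose reads can be shared with pseudogenes, had 10 of 34 raised (28 adjusted over the list alone, adjusted p = 5.4e-09). Oxidative phosphorylation genes had 3 of 33 raised (2 adjusted over the list alone, adjusted p = 1.9e-05), and mitosis genes 4 of 31 (3 adjusted over the list alone, adjusted p = 3e-04). Heat shock genes had 2 of 16 raised with 1 lowered (7 and 1 adjusted over the list alone, adjusted p = 0.019). Each of these 4 lists had adjusted p = 0.97 with an estimated correlation. After quantile normalization the mitosis and heat shock lists had adjusted p = 0.15 and 0.19. Immediate early genes had 2 raised and 6 lowered of 25 (2 and 6 adjusted over the list alone, adjusted p = 0.52), among them Fosl1 (-1.51 ± 0.19). DNA replication genes had 3 raised and 2 lowered of 32 (3 and 2 adjusted over the list alone, adjusted p = 0.93), and were lower as a list after quantile normalization (adjusted p = 0.043). Mitochondrially encoded transcripts had 0 of 15 called (0 adjusted over the list alone, adjusted p = 0.34). Of the OP9 stromal markers 1 of 13 fell, the BMP antagonist gene Grem1 (-1.28 ± 0.29; 1 adjusted over the list alone, adjusted p = 0.3). The 6 h library 2 stands apart from the 6 h libraries 1 and 3 (chi-square per gene of 32.55 and 18.83, against 5.52 between those). It held more of Cxcl12 (504 against 178 and 258) and Pdgfra (22.2 against 8.31 and 15.3). MEEC grown without OP9 cells in the third experiment, normalized separately, also held Cxcl12 (118 to 260) and Pdgfra (3.82 to 7.98). These transcripts are therefore not of the feeder cells alone. The total of 2660 became 1273 without the 6 h library 2, and 1602 and 1580 without the 24 h libraries 1 and 2.

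Whether the ligand effects differed between 24 h and 6 h was tested as an interaction. Fbln5 was the 1 gene called for either ligand, its log2 fold change at 24 h minus that at 6 h being -0.67 ± 0.10 for Dll4 (adjusted p = 0.04) and -0.79 ± 0.10 for Jag1 (adjusted p = 0.0049). For Jag1 the call held in 12 of the 12 fits that left out 1 library, for Dll4 in 2. The Dll4 count of 1 became 0 in each of those fits except without the 6 h libraries OP9-GFP 2 (1) and OP9-Dll4 3 (4). It was also 0 with edgeR, after quantile normalization and without the mean-variance trend, while the Jag1 count stayed at 1 in these 3. The Notch targets had 0 of 8 called for Dll4 (0 adjusted over the list alone, adjusted p = 0.076) and 0 for Jag1 (1 adjusted over the list alone, adjusted p = 0.021, and adjusted p = 0.13 with an estimated correlation).

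The second experiment asked what blocking the active Notch fragment changed in MEEC over OP9-GFP, without added ligand. After RO4929097, Il33 stood at 8.17 ± 0.58 against 39.8 ± 8.28 in vehicle (log2 fold change -2.13 ± 0.13, adjusted p = 5.2e-05). The kinesin gene Kif26b stood at 20.1 ± 1.89 against 69.7 ± 3.83 (-1.74 ± 0.07, adjusted p = 2.1e-06). The collagen gene Col5a3 changed by -1.28 ± 0.19, the metalloprotease gene Adam12 by -1.21 ± 0.12 and the activin antagonist gene Fst by -0.94. Among Notch targets, Hes1 fell to 23.8 ± 3.28 from 45.3 ± 4.21 (-0.90 ± 0.10, adjusted p = 0.0029). Nrarp fell to 4.70 ± 0.51 from 9.05 ± 0.95 (-0.82 ± 0.11, adjusted p = 0.0068), Hey2 to 6.13 ± 0.48 from 10.2 ± 0.89 (-0.64 ± 0.09, adjusted p = 0.011) and Hey1 to 1.12 ± 0.30 from 2.41 ± 0.29 (-0.70 ± 0.14, adjusted p = 0.049). Jag1 fell by 0.46 ± 0.07 (adjusted p = 0.013), while Notch1 did not pass (-0.19, adjusted p = 0.6). Among the 29 genes that rose were Dlk1, which encodes a non-canonical Notch ligand (0.99 ± 0.20, adjusted p = 0.049), and the cyclin gene Ccnd1 (0.55 ± 0.07, adjusted p = 0.0068), and 89 fell.

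By list, 4 of 6 Notch targets fell with the inhibitor (4 fell and 1 rose adjusted over the list alone, adjusted p = 1.5e-05, and adjusted p = 0.093 with an estimated correlation). Cholesterol biosynthesis genes rose, 5 of 25 (21 adjusted over the list alone, adjusted p = 8.2e-23, and adjusted p = 0.18 with an estimated correlation), including the sterol oxidase gene Msmo1 (90.1 ± 12.6 against 60.5 ± 2.92, 0.56 ± 0.09). Extracellular matrix genes fell, 3 of 35 (11 adjusted over the list alone, adjusted p = 1.7e-10, and adjusted p = 0.18 with an estimated correlation), including the collagen cross-linking enzyme gene Lox (-0.69 ± 0.11). Of 29 BMP and TGF-beta genes 3 fell, Tgfb2 (-0.71 ± 0.07) and Ccn2 (-0.79 ± 0.13) among them (7 fell and 3 rose adjusted over the list alone, adjusted p = 0.019, and adjusted p = 0.27 with an estimated correlation). Smooth muscle and contractile genes had 0 of 19 called (2 lowered adjusted over the list alone, adjusted p = 5.2e-05, and adjusted p = 0.27 with an estimated correlation). Immediate early genes had 1 of 25 raised (1 raised and 1 lowered adjusted over the list alone, adjusted p = 0.09, or 0.0044, lower, with the replicate number as a block). OP9 stromal markers had 0 of 10 called (0 adjusted over the list alone, adjusted p = 0.94). The libraries numbered 1 of both groups held more of the chemokine transcript Cxcl12 than the rest, 931 and 1030 against at most 287. MEEC grown without OP9 cells in the third experiment held it as well.

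With the replicate number as a block 427 genes changed with the inhibitor. The count of 118 became 58, 48 and 53 without vehicle libraries 2, 3 and 4, and 50 and 53 without inhibitor libraries 2 and 3. Without the libraries numbered 1, an alternative chosen after seeing the data, 75 genes changed. Il33, Kif26b, Hes1, Nrarp, Tgfb2 and Ccnd1 kept their calls in 8 of the 8 fits that left out 1 library, Hey2, Jag1, Col5a3 and Fst in 7, Msmo1 in 6, Lox in 5, Ccn2 in 3, Dlk1 in 1 and Hey1 in 0.

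On recombinant rJAG1, 647 genes rose and 638 fell against vehicle. Il33 stood at 227.1 ± 14.8 against 20.6 ± 6.35 (log2 fold change 3.45 ± 0.17, adjusted p = 1.2e-08) and Dsg2 at 33.7 ± 1.01 against 2.43 ± 0.58 (3.36 ± 0.14). Hey1 stood at 16 ± 3.05 against 0.773 ± 0.0376 (3.25 ± 0.14, adjusted p = 2.4e-09), Hey2 at 35.6 ± 3.87 against 6.65 ± 3.6 (2.35 ± 0.25, adjusted p = 1.4e-05) and Nrarp at 19.6 ± 5.44 against 3.18 ± 0.51 (2.28 ± 0.23, adjusted p = 1.1e-05). Hes1 rose by 1.07 ± 0.14 (adjusted p = 1e-04) and Jag1 by 1.40 ± 0.15 (adjusted p = 1.9e-05). Notch1 did not pass (0.56 ± 0.19, adjusted p = 0.089, or 0.023 with the replicate number as a block). The water channel gene Aqp1 (chromosome 6, 55336432 to 55348555, plus strand) fell to 0.259 ± 0.162 from 5.37 ± 2.10 (-2.29 ± 0.22). The angiopoietin-like gene Angptl7 fell to 0.775 ± 0.277 from 11.9 ± 7.56 (-2.66 ± 0.41, adjusted p = 0.00045) and the guidance factor gene Sema3c to 127.6 ± 7.47 from 404.9 ± 95.3 (-1.63 ± 0.14, adjusted p = 1.7e-06).

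Of 8 Notch targets 5 rose on rJAG1 (6 adjusted over the list alone, adjusted p = 9.8e-08, or 0.0033 with an estimated correlation). Genes of epithelial to mesenchymal transition had 11 of 25 raised and 1 lowered (15 and 2 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.078 with an estimated correlation), including the mesenchymal factor gene Prrx1 (1.76 ± 0.20), the matricellular gene Postn (1.39 ± 0.17) and the membrane metalloprotease gene Mmp14 (1.02 ± 0.13). BMP and TGF-beta genes had 6 of 29 raised and 2 lowered (7 and 3 adjusted over the list alone, adjusted p = 0.023, and adjusted p = 0.33 with an estimated correlation), including Tgfb2 (1.24 ± 0.08), Ltbp1, which encodes a TGF-beta binding protein (1.82 ± 0.09), and Bmp2 (1.07 ± 0.15). Of 26 endocardial secreted factors 11 rose and 7 fell (the same counts adjusted over the list alone, adjusted p = 0.28), with Wnt2 (1.98 ± 0.19) and the growth factor gene Igf2 (1.59 ± 0.17) among those that rose. Extracellular matrix genes had 13 of 34 raised and 4 lowered (14 and 6 adjusted over the list alone, adjusted p = 0.0016, and adjusted p = 0.43 with an estimated correlation), with Fbln5 among those lowered (-0.92 ± 0.07). The p53 response had 7 of 20 raised and 1 lowered (8 and 1 adjusted over the list alone, adjusted p = 3.3e-05, and adjusted p = 0.12 with an estimated correlation), Cdkn1a standing at 71.8 ± 5.94 against 33.2 ± 4.52 (1.1 ± 0.11). Mitosis genes had 3 of 31 lowered (11 adjusted over the list alone, adjusted p = 9.8e-08, and adjusted p = 0.33 with an estimated correlation), such as the spindle motor gene Kif11 (-0.29 ± 0.08). Genes of amino acid stress and unfolded protein response had 9 of 30 raised (11 adjusted over the list alone, adjusted p = 1.1e-05, and adjusted p = 0.33 with an estimated correlation). Hypoxia and glycolysis genes had 6 of 30 lowered (7 adjusted over the list alone, adjusted p = 0.00051, and adjusted p = 0.43 with an estimated correlation). Epithelial markers had 4 of 6 raised (4 raised and 1 lowered adjusted over the list alone, adjusted p = 1.2e-05, and adjusted p = 0.078 with an estimated correlation), including the keratin gene Krt14 (947 ± 72.1 against 472.1 ± 26.0, 1.00 ± 0.08) and the E-cadherin gene Cdh1 (1.99 ± 0.18).

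On rDLL4, 328 genes rose and 141 fell. Il33 stood at 120.5 ± 15.3 (log2 fold change 2.54 ± 0.17, adjusted p = 1.3e-06), Dsg2 at 15.9 ± 2.36 (2.31 ± 0.14). Hey1 stood at 5.89 ± 0.64 (1.95 ± 0.14, adjusted p = 2.1e-06), Hey2 at 20.7 ± 1.69 (1.60 ± 0.25, adjusted p = 0.0016). Hes1 stood at 50.3 ± 4.70 against 29.7 ± 2.50 (0.74 ± 0.14, adjusted p = 0.0067), Nrarp at 8.24 ± 3.21 (1.09 ± 0.23, adjusted p = 0.016) and Kif26b at 160.2 ± 12.5 against 48.8 ± 13.4 (1.73 ± 0.17). Aqp1 fell to 0.897 ± 0.282 (-1.70 ± 0.22, adjusted p = 0.00028), the hypoxia-inducible mitophagy gene Bnip3 by 1.1 ± 0.12 and Fbln5 by 0.56 ± 0.07. Of 8 Notch targets 5 rose (6 adjusted over the list alone, adjusted p = 7.6e-09, or 0.0019 with an estimated correlation). Of 25 genes of epithelial to mesenchymal transition 6 rose (11 raised and 1 lowered adjusted over the list alone, adjusted p = 1.1e-07, or 0.028 with an estimated correlation). Interferon response genes had 10 of 32 raised (14 adjusted over the list alone, adjusted p = 8.5e-14, or 0.038 with an estimated correlation), including the ubiquitin-like modifier gene Isg15 (20.2 ± 0.79 against 8.64 ± 1.03, 1.15 ± 0.15, adjusted p = 0.00038) and its protease gene Usp18 (1.1 ± 0.18). On rJAG1 that list had 4 raised (11 raised and 1 lowered adjusted over the list alone, adjusted p = 0.00034, and adjusted p = 0.33 with an estimated correlation). Extracellular matrix genes had 12 of 34 raised and 1 lowered on rDLL4 (15 and 2 adjusted over the list alone, adjusted p = 2.4e-08, and adjusted p = 0.18 with an estimated correlation), Col5a1 by 0.70 ± 0.06. Epithelial markers had 4 of 6 raised (4 raised and 1 lowered adjusted over the list alone, adjusted p = 2.4e-05, and adjusted p = 0.073 with an estimated correlation), Cdh1 by 1.38 ± 0.18 and Krt14 by 0.57 ± 0.08. Both kept their calls in all 6 fits that left out 1 library. The p53 response had 5 of 20 raised (6 adjusted over the list alone, adjusted p = 0.00021, and adjusted p = 0.16 with an estimated correlation), Cdkn1a by 0.69 ± 0.11.

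With the replicate number as a block, 2022 genes changed on rJAG1 and 868 on rDLL4. Library weights gave 2847 and 1846, and fitting only the 2 groups named gave 554 and 157. Vehicle library 3 stands apart from vehicle libraries 1 and 2 (chi-square per gene of 35.42 and 52.63, against 11.11 between those), and without it 1885 genes changed on rJAG1. Grouping it with rJAG1 libraries 1 and 3 against the rest gave 948 genes, so part of the spread runs across the 2 groups. In that rest, rJAG1 library 2 also stands apart from rJAG1 libraries 1 and 3 (chi-square per gene of 18.11 and 22.32, against 6.96 between those). The rDLL4 count of 469 became 312 and 758 without vehicle libraries 2 and 3, and 239, 303 and 287 without rDLL4 libraries 1, 2 and 3. Il33, Dsg2, Hey1, Hey2 and Isg15 kept their calls in all 6 such fits and Nrarp in 3. Kif11 kept its call on rJAG1 in 3 of 6.

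Directly compared, rDLL4 exceeded rJAG1 in 14 genes and was lower in 17. The amounts of ligand on the wells were not given. Heyl (-1.51 ± 0.16, adjusted p = 0.001), Hey1 (-1.29 ± 0.14, adjusted p = 0.0012) and Dsg2 (-1.05 ± 0.14, adjusted p = 0.0036) were lower on rDLL4. Mmrn1, which encodes a platelet and endothelial multimerin, was higher (1.09 ± 0.14, adjusted p = 0.0031), as was Sema3c (0.89 ± 0.14, adjusted p = 0.013). Hey2 did not pass (-0.75 ± 0.25, adjusted p = 0.38, or 0.04 with the replicate number as a block), nor did Nrarp (-1.19 ± 0.23, adjusted p = 0.053, or 0.0024 with the block). Of 8 Notch targets 2 were lower on rDLL4 (5 adjusted over the list alone, adjusted p = 1.2e-06, or 0.0064 with an estimated correlation). Mitosis genes were higher on rDLL4 as a list, with 0 of 31 called (0 adjusted over the list alone, adjusted p = 1e-04, and adjusted p = 0.4 with an estimated correlation). With the block 118 genes differed, with library weights 85, with only the 2 groups fitted 8, and edgeR called 17. The count of 31 became 12 without rDLL4 library 2 or 3, and 13 and 17 without rJAG1 libraries 1 and 2. Heyl, Hey1, Dsg2 and Mmrn1 kept their calls in all 6 such fits and Sema3c in 4.

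RO4929097 was added to each ligand to block the Notch activity that the ligand raised. The libraries of each ligand alone also served against vehicle, so a rise on a ligand and its fall with the inhibitor are not independent. On rJAG1 with the inhibitor, 1284 genes were higher and 1177 lower than on rJAG1 alone. Il33 fell to 17.2 ± 2.23 (log2 fold change -3.65 ± 0.17, adjusted p = 2.2e-09), Hey1 to 0.586 ± 0.151 (-3.41 ± 0.14, adjusted p = 7.2e-10). Dsg2, Nrarp and Notch1 changed by -3.63, -2.73 ± 0.23 and -0.76 ± 0.19, while Aqp1 rose to 14.2 ± 2.07 (3.59 ± 0.22, adjusted p = 2.4e-08) and Dlk1 by 2.83. On rDLL4 with the inhibitor, 658 genes were higher and 772 lower than on rDLL4 alone. Kif26b fell to 18.2 ± 3.24 (-3.08 ± 0.17, adjusted p = 1.9e-08), Il33 to 19.9 ± 1.16 (-2.54 ± 0.17), Hey1 to 0.751 ± 0.0989 (-1.97 ± 0.14, adjusted p = 4.5e-07), and Aqp1 rose to 17.6 ± 1.88 (3.30 ± 0.22, adjusted p = 1.8e-07). Of 8 Notch targets, 5 fell and 1 rose with the inhibitor on each ligand. On rDLL4 6 fell and 1 rose adjusted over the list alone, and on rJAG1 5 and 1 (list adjusted p = 1.7e-05 and 2.5e-05, or 0.018 and 0.017 with an estimated correlation). Interferon response genes had 16 of 32 lowered and 1 raised on rDLL4 (20 and 2 adjusted over the list alone, adjusted p = 2.8e-10, and adjusted p = 0.053 with an estimated correlation), Isg15 changing by -1.38 ± 0.15. The p53 response had 12 of 20 lowered and 1 raised on rJAG1 (15 and 1 adjusted over the list alone, adjusted p = 8.3e-07, and adjusted p = 0.05 with an estimated correlation), Cdkn1a changing by -1.45. BMP and TGF-beta genes had 8 of 29 lowered and 5 raised on rDLL4 (12 and 7 adjusted over the list alone, adjusted p = 0.054, or 0.016 with the replicate number as a block). Epithelial markers had 4 of 6 lowered on rDLL4 and 5 on rJAG1 (5 and 5 adjusted over the list alone, adjusted p = 2.3e-09 and 7.2e-08, or 0.018 and 0.03 with an estimated correlation), Cdh1 changing by -2.17 ± 0.18 and -2.71 ± 0.18. Cardiomyocyte markers had 1 raised and 1 lowered of 6 on each ligand, Myl7 (0.91 ± 0.19 and 1.05 ± 0.19) and Tnnt2 (-0.85 ± 0.17 and -0.81 ± 0.17). As a list they had adjusted p = 0.24 and 0.6 (1 raised on each and 2 and 1 lowered adjusted over the list alone). Cdh1, Myl7 and Tnnt2 kept these calls in all 6 fits that left out 1 library. With the block 2315 genes changed on rDLL4, and without rDLL4 with inhibitor library 2 the count of 1430 became 929.

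The change with the inhibitor differed between the ligands in 2 genes, Hey1 (difference 1.44 ± 0.20, adjusted p = 0.026) and Heyl (1.56 ± 0.22, adjusted p = 0.026), both lowered less on rDLL4. Both stood lower on rDLL4 than on rJAG1 without the inhibitor, and Hey1 with it stood near vehicle on each ligand. The difference mostly restates that gap and does not show that RO4929097 acted differently on the ligands. Hey1 and Heyl kept their calls in 2 and 1 of the 12 fits that left out 1 library. The Notch targets differed as a list (2 of 8 called, 3 adjusted over the list alone, adjusted p = 1.1e-05, or 0.013 with an estimated correlation). The count of 2 was 0 with edgeR and in each fit that left out 1 library except without rJAG1 library 2 (3) or 3 (1). With the replicate number as a block it was 1.

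Against vehicle, ligand and inhibitor together left 74 genes higher and 114 lower for rDLL4, and 50 higher and 76 lower for rJAG1. Hey1 stood at 0.751 ± 0.0989 and 0.586 ± 0.151 against 0.773 ± 0.0376 in vehicle, with log2 differences of -0.02 (adjusted p = 0.98) and -0.16 (adjusted p = 0.83). Of 8 Notch targets 0 were called in either (1 raised and 1 lowered in each adjusted over the list alone, adjusted p = 0.6 and 0.73). The annexin gene Anxa8 (chromosome 14, 34085981 to 34100571, plus strand) fell to 45.0 ± 4.49 and 46.1 ± 2.47 from 143.9 ± 17.7 (-1.65 ± 0.12, adjusted p = 4.2e-06, and -1.61 ± 0.12, adjusted p = 5.7e-06). The endothelial phosphatase gene Ptprb changed by -1.53 ± 0.18 and -1.53, the proteoglycan gene Vcan by -1.03 and -1.32, and Aqp1 by 1.60 ± 0.22 and 1.31 ± 0.22. Epithelial markers had 5 and 4 of 6 lowered (5 and 5 adjusted over the list alone, adjusted p = 3.9e-12 and 1.7e-13, or 0.013 and 0.0087 with an estimated correlation), Krt14 changing by -1.07 ± 0.08 and -0.82 ± 0.08. Hypoxia and glycolysis genes had 4 and 3 of 30 lowered (13 and 13 adjusted over the list alone, adjusted p = 1.1e-10 and 1.6e-11, and adjusted p = 0.28 and 0.22 with an estimated correlation), among them the phosphofructokinase gene Pfkl (-0.79 ± 0.11 and -0.93 ± 0.11).

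With the replicate number as a block these counts were 587 and 389. Library weights gave 1806 and 1796, and fitting only the 2 groups named gave 22 and 16, so the counts depend strongly on how the spread is estimated. For rDLL4 with inhibitor the count of 188 became 88 and 301 without vehicle libraries 1 and 2, and 113, 74 and 71 without its own libraries 1, 2 and 3. For rJAG1 with inhibitor the count of 126 became 68 without vehicle library 1, and 72, 82 and 46 without its own libraries 1, 2 and 3. Anxa8, Ptprb and Aqp1 kept their calls in all 6 such fits of each.

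Genes called in one experiment were then followed in the libraries of the others. Of the 100 genes most raised by OP9-Jag1 at 24 h, 96 were measured in the third experiment. Of these, 93 were higher on rJAG1 (82 raised, median log2 fold change 1.2, adjusted p = 2.2e-07 with an estimated correlation) and 93 were higher on rDLL4 (65 raised, median 0.79, adjusted p = 2.2e-07). With the inhibitor, 93 were lower on rJAG1 (85 lowered, median -1.42, adjusted p = 4.4e-07) and 93 lower on rDLL4 (77 lowered, median -0.98, adjusted p = 5.7e-07). The rise and the fall on a ligand share that ligand's libraries, so they are not independent of each other. In the inhibitor co-culture 87 of 91 measured were lower (28 lowered, median -0.45, adjusted p = 6.4e-05). The 89 genes lowered by the inhibitor over OP9-GFP were mostly higher with each ligand, 76 over OP9-Dll4 at 6 h (median 0.24, adjusted p = 0.0019) and 81 of 87 on rJAG1 (median 1.00). Of the 100 genes most lowered by OP9-Jag1 at 24 h, 93 were lower on rJAG1 (72 lowered, median -0.66, adjusted p = 8.7e-05). In the inhibitor co-culture 73 of 97 measured were higher (2 raised and 1 lowered, median 0.11), which did not pass with an estimated correlation (adjusted p = 0.071).

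**Figure D3:**
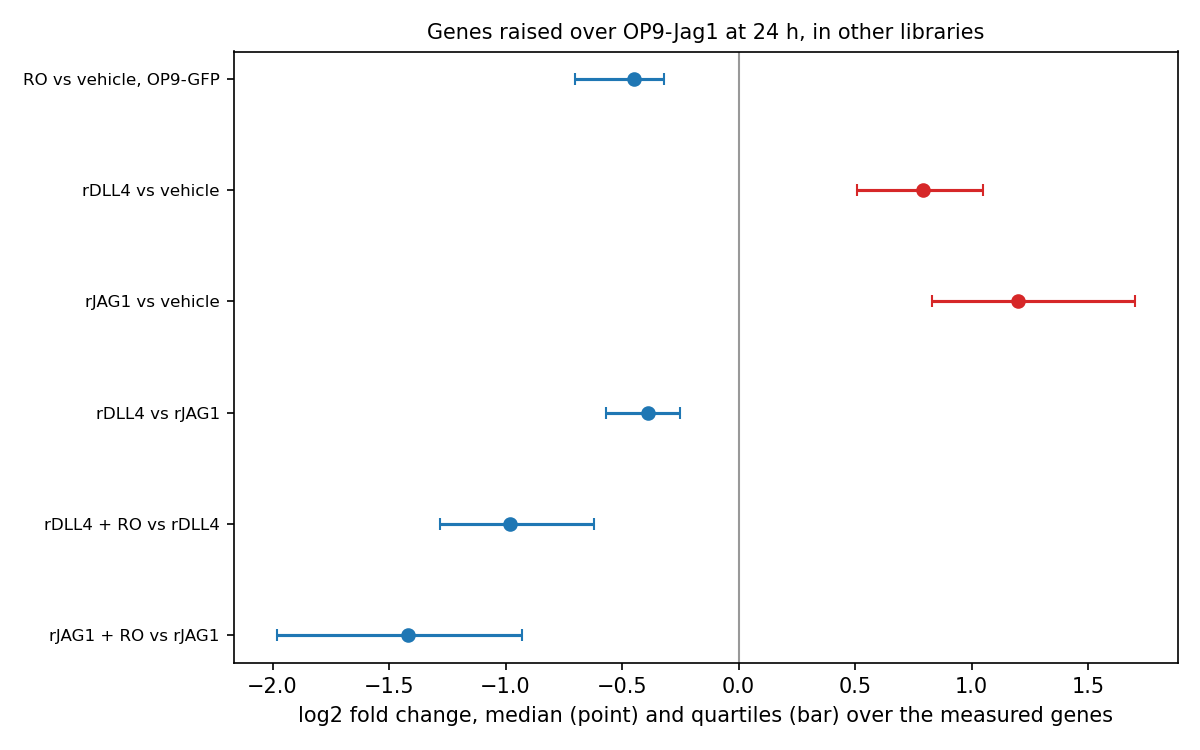
Log2 fold changes, as medians with quartiles, of the genes most raised by OP9-Jag1 at 24 h in 6 contrasts from libraries that played no part in choosing them. The median is 1.2 on rJAG1, 0.79 on rDLL4 and -0.45 with RO4929097 over OP9-GFP.

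Within an experiment the ligands share their control libraries, which alone gives correlated fold changes. The correlation across genes (which are not independent replicates) of the rDLL4 and rJAG1 effects was 0.83 against 0.5 in simulations of unchanged groups, with a covariance of 0.0599 against 0.0119. In addition, 305 genes rose on both, where independent lists would share 15.8. For OP9-Dll4 and OP9-Jag1 at 24 h the correlation was 0.75 against 0.5, and the covariance 0.0291 against 0.012. There 30 genes rose in both against 0.384. Part of these excesses may come from the shared controls, which were too few to divide.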

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

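Apart from the splits of the libraries, the comparison of spreads and the count without the vehicle library numbered 3, the tests in this part were chosen after the result was seen.

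Fbln5 is marked because the effect of each ligand on it differed between the time points, by -0.67 for Dll4 and -0.79 for Jag1 (log2, 24 h minus 6 h). Heyl and Hey1 are marked because the change with RO4929097 differed between the ligands, by 1.56 and 1.44, which mostly restates their gap without the inhibitor. Within groups of 4 libraries, 5 of 56 gene and group pairs tested had a library far from the others by Dixon's test, where chance marks about 1 in 20 (2.8 of 56). Rap1gap2 was 8.91 in vehicle library 2 against 6.8 to 7.04 in the other vehicle libraries, and Ank1 was 19.7 in inhibitor library 1 against 22.3 to 22.7. Cxcl12 was 931 in vehicle library 1 against 176 to 252 and 1030 in inhibitor library 1 against 194 to 287. Pdgfra was 32.9 in vehicle library 1 against 12.9 to 15.5.

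Other splits of the libraries were counted for each comparison. With RO4929097 over OP9-GFP, the real split was the only 1 of 35 to give as many as 118 genes, the highest other giving 21. That count takes all libraries as interchangeable, whereas the numbers pair them. The splits that part as many pairs are 8, too few for a share under 0.05, and the highest other of them gave 2. For the other pairwise comparisons, 10 splits are too few for a share under 0.05. The real split was the only 1 to give as many genes for OP9-Jag1 at 6 h (14, highest other 2), OP9-Dll4 at 24 h (71, highest other 0), OP9-Jag1 at 24 h (281, highest other 1), OP9-Dll4 against OP9-Jag1 at 24 h (4, highest other 0) and OP9-GFP at 24 h against 6 h (2660, highest other 1). The same held for rDLL4 (469, highest other 1), rDLL4 against rJAG1 (31, highest other 0), rDLL4 with inhibitor against rDLL4 (1430, highest other 0) and against vehicle (188, highest other 0), and rJAG1 with inhibitor against rJAG1 (2461, highest other 0) and against vehicle (126, highest other 1). For OP9-Dll4 at 6 h 2 of the 10 splits gave at least the 1 gene found (highest other 1), and for OP9-Dll4 against OP9-Jag1 at 6 h all 10 gave at least 0 (highest other 1). For rJAG1 the real split (1285) was also the only 1 to give as many, but the highest other gave 948, a split that sets rJAG1 libraries 1 and 3 and vehicle library 3 against the rest. It points to a structure of the samples, with the cytoskeletal genes Myh9 (0.75) and Flna (0.65) among those that differed. Among 100 drawn splits of each interaction, 18 gave at least the 1 gene of Dll4 by time (highest other 124), 13 at least the 1 of Jag1 by time (highest other 360) and 9 at least the 2 of inhibitor by ligand (highest other 3642). The high counts point to a structure of the samples, since such splits turn differences between groups into an interaction. For the same reason these splits do not decide whether chance gave the counts of 1, 1 and 2.

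Among the co-cultures, heart and blood transcripts stood out in 4 of the 6 OP9-Dll4 libraries. Hbb-bs also had 5 to 34 reads in each library of the third experiment, so it does not by itself mark these cultures. Induction by Dll4 in every culture by 6 h is argued against, because 2 of the 3 libraries at 6 h held none of Myh7, Actc1 and Myl2 above the highest library without Dll4. At 24 h each OP9-Dll4 library held them (Myh7 265, 96 and 98 reads), so induction in every culture by 24 h is not argued against. RNA or cells of heart and blood carried into those libraries may be the source. This requires a fixed ratio among the cardiac transcripts if 1 kind of heart RNA was carried, and of these to Hbb-bs only if heart and blood came in 1 mixture. A chi-square count test over 5 OP9-Dll4 libraries with reads gave a permutation p = 0.3 for Myh7, Actc1, Myl2 and Hbb-bs, and a permutation p = 0.0025 with Ttn over 6 libraries. Without Hbb-bs it gave a permutation p = 0.45 for Myh7, Actc1 and Myl2, and a permutation p = 0.0048 with Ttn. Ttn was left out after its values were seen, and this form of the test followed earlier forms. Libraries without Dll4 also held 1 to 6 reads of Ttn, and the 6 h OP9-Dll4 libraries 1 and 2 held 2 and 3. The tests with Ttn take in these background reads. Their low p therefore does not show that the ratio differed among the libraries that carried the transcripts. These tests take reads as independent and cover counting error only, whereas libraries of a group differ by more (chi-square per gene of 5.52 to 52.63 in pairs of them). A low p therefore does not exclude a fixed ratio, so a shared source of RNA and another origin cannot be told apart. An effect of Dll4 by 24 h, or in part of the cultures, stays open as well.

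Fewer genes changed on rDLL4 than on rJAG1 (469 against 1285). The ratio of median SDs, rDLL4 to rJAG1, was 0.702. It cannot explain these counts either way, because all groups shared 1 estimate of the spread per gene. Fits of only the groups named, where it could matter, also gave fewer genes on rDLL4 despite its smaller spread. Lower depth is argued against by a ratio of median reads, rDLL4 to rJAG1, of 1.11. A smaller response of the genes that rJAG1 changes is in line with the OP9-Jag1 list from other libraries, of which 91 of 96 genes were lower on rDLL4 than on rJAG1 (median -0.39, adjusted p = 9.2e-07 with an estimated correlation). Whether the ligands differ in potency or were attached in different amounts was not tested, and nothing in the design separates these.

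Some genes lay below vehicle when ligand and inhibitor were given together. Chance values of the shared vehicle libraries that vary gene by gene are argued against. Of the measured genes lowered with rDLL4 and inhibitor, 89.7% were also lower in the inhibitor co-culture (87 of 97). The median there was -0.23, with list adjusted p = 0.0032 with an estimated correlation. A vehicle library that deviates over many genes together could lean the same way, and the test does not address this. Without vehicle library 3, which stands apart, 164 genes were called for rDLL4 with inhibitor against 188 with it (47 without the libraries numbered 3 of every group). These totals count both directions, and 114 of the 188 were lower. They do not show how many of the genes below vehicle stayed called, so that library as the cause stays open. Notch signalling present without added ligand may be what the inhibitor removed, and then these genes should rise over OP9-Jag1 at 24 h: 57 of 100 were higher (median 0.03, 7 raised and 3 lowered). That list passed with the preset correlation (adjusted p = 0.012, or 0.0088 with the replicate number as a block) and not with an estimated correlation (adjusted p = 0.25). Of the genes lowered with rJAG1 and inhibitor, 38 of 76 were higher there (median 0, adjusted p = 0.55, or 0.72 with an estimated correlation). The 89 genes lowered by the inhibitor over OP9-GFP were tested with an estimated correlation too. Over OP9-Jag1 at 24 h, 77 were higher (median 0.42, adjusted p = 0.00067). Of the 87 measured in the third experiment, 79 were below vehicle with rDLL4 and inhibitor (median -0.28, adjusted p = 0.00023). With rJAG1 and inhibitor 73 were below it (median -0.26, adjusted p = 0.00024). These genes moved as a loss of Notch signalling requires. The lists differ, which leaves this open for the genes below vehicle as a whole. An effect of RO4929097 apart from Notch was not tested.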

How the results depend on the processing

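The replicate block within each time, the fits without the 6 h libraries numbered 2, without the libraries numbered 1 of the second or 3 of the third experiment, and without the cardiac and erythroid transcripts were chosen after seeing the data. The cause of the changes was not tested, except that leaving out libraries or groups, or asking for a larger fold change, leaves fewer samples or genes. Below, counts of genes changed are given for settings that moved them by more than 1.5 times.

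With the replicate number as a block the counts were 7 (OP9-Dll4 at 6 h), 82 (OP9-Jag1 at 6 h), 247 (OP9-Dll4 at 24 h), 628 (OP9-Jag1 at 24 h), 7 (OP9-Dll4 against OP9-Jag1 at 24 h), 4534 (OP9-GFP, 24 h against 6 h), 2 (Jag1 by time), 427 (inhibitor over OP9-GFP), 868 (rDLL4), 2022 (rJAG1), 118 (rDLL4 against rJAG1), 2315 (rDLL4 with inhibitor against rDLL4), 587 and 389 (rDLL4 and rJAG1 with inhibitor against vehicle) and 1 (inhibitor by ligand). Blocked within each time, the OP9-Dll4 counts were 162 and 808 at 6 h and 24 h, the OP9-Jag1 counts 467 and 1512, and their difference at 24 h 67 genes. Over OP9-GFP the numbers do not pair the samples between times (correlations 0.04 to 0.17). For the interactions they pair some libraries and not all. The block moved 184 of 2159 gene results past the threshold and 1 below it, and of 460 list results 18 and 3, and changed no other call.

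The weights of the first experiment come from an estimate that stopped before it converged. With library weights the counts were 113 and 594 (OP9-Dll4 and OP9-Jag1 at 6 h), 194 (their difference), 222 and 568 (the same ligands at 24 h), 4527 (OP9-GFP), 5 (Jag1 by time), 1846 and 2847 (rDLL4 and rJAG1), 85 (their difference), 2584 (rDLL4 with inhibitor against rDLL4), 1806 and 1796 (both ligands with inhibitor against vehicle) and 12 (inhibitor by ligand). Fitting only the groups named gave 1 (OP9-Jag1 at 6 h), 1 (OP9-Dll4 against OP9-Jag1 at 6 h), 0 (the same at 24 h), 1506 (OP9-GFP), 2 (Jag1 by time), 157 and 554 (rDLL4 and rJAG1), 8 (their difference), 22 and 16 (both with inhibitor against vehicle) and 5 (inhibitor by ligand). Asking for an absolute log2 fold change of at least 1 gave 0 and 1 (OP9-Dll4 and OP9-Jag1 at 6 h), 15 and 44 (at 24 h), 165 (OP9-GFP), 0 and 0 (ligands by time), 13 (inhibitor over OP9-GFP), 72 and 234 (rDLL4 and rJAG1), 10 (their difference), 259 and 440 (inhibitor on rDLL4 and rJAG1), and 29 and 20 (both with inhibitor against vehicle).

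By edgeR, 46 genes changed over OP9-Dll4 at 24 h, 0 between OP9-Dll4 and OP9-Jag1 at 24 h (4 by limma, 267 at an unadjusted p under 0.05), 0 for Dll4 by time (1 by limma, 390 at an unadjusted p under 0.05), 17 between rDLL4 and rJAG1, and 0 for inhibitor by ligand (2 by limma, 496 at an unadjusted p under 0.05). The stricter filter gave 0 for OP9-Dll4 against OP9-Jag1 at 24 h and for inhibitor by ligand, and a pseudocount of 0.25 gave 0 for the latter. Quantile normalization gave 24 for OP9-Jag1 at 6 h and 0 for Dll4 by time, where a fit without the mean-variance trend also gave 0, as it did for OP9-Dll4 at 6 h. Without the 6 h libraries numbered 2 the counts were 0 and 5 (OP9-Dll4 and OP9-Jag1 at 6 h). Without cardiac and erythroid transcripts they were 45 (OP9-Dll4 at 24 h) and 0 (against OP9-Jag1). Without the libraries numbered 1 the inhibitor over OP9-GFP changed 75 genes. Without the libraries numbered 3, 8 genes differed between rDLL4 and rJAG1, 47 and 43 changed with rDLL4 or rJAG1 and inhibitor against vehicle, and 0 for inhibitor by ligand. The setting without a filter removed no gene and tests nothing.

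Leaving out each library in turn gave 0 to 1 genes (OP9-Dll4 at 6 h), 1 to 10 (OP9-Jag1 at 6 h), 0 to 0 (their difference), 10 to 81 and 114 to 293 (OP9-Dll4 and OP9-Jag1 at 24 h), 0 to 7 (their difference), 1273 to 2995 (OP9-GFP), 0 to 4 and 1 to 1 (Dll4 and Jag1 by time), 48 to 104 (inhibitor over OP9-GFP), 239 to 758 and 983 to 1885 (rDLL4 and rJAG1), 12 to 29 (their difference), 929 to 1084 and 1690 to 2443 (inhibitor on rDLL4 and rJAG1), 71 to 301 and 46 to 158 (both with inhibitor against vehicle) and 0 to 3 (inhibitor by ligand). Over these fits 960 gene results fell below the threshold, 94 passed it and 0 turned direction. The DNA replication list, higher at 24 h than at 6 h over OP9-GFP with adjusted p = 0.93, was lower with adjusted p = 0.043 after quantile normalization. With an estimated correlation 132 of 460 list results and 18 of 74 tests of transferred lists lost their call. With fry, 97 of the 460 list results lost their call and 8 gained one. Depth limits genes near the floor of 3 reads, such as Heyl, Myl2 and Actc1 in the control groups.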

Other observations

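The values of this part were picked after they were seen, and no further test was run on them beyond leaving out libraries.

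Ligand genes measured in the co-cultures include Jag1 itself, which the OP9-Jag1 cells carry. Its signal was 51.2 ± 4.97 over OP9-Jag1 and 49.2 ± 10.1 over OP9-Dll4 at 6 h, and 65.6 ± 3.38 and 59.6 ± 1.91 at 24 h (SD, n = 3). The species and sequence of the ligand constructs were not given in the sources used here. The chemokine transcript Cxcl12 is abundant in stroma, though MEEC grown without OP9 cells also held it (118 to 260 in the third experiment). It was 504, 332 and 279 in the 6 h libraries numbered 2 over OP9-GFP, OP9-Dll4 and OP9-Jag1. In the other 6 h libraries of that experiment it lay between 178 and 258.

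Some further genes moved on recombinant ligand, picked singly and not as a list (log2 fold changes against vehicle, ± SE). Nrp1, a semaphorin and VEGF co-receptor gene, rose by 0.54 ± 0.13 on rDLL4 (adjusted p = 0.034) and by 0.67 ± 0.13 on rJAG1 (adjusted p = 0.0033). Genes of feedback on receptor tyrosine kinases, Spry2 and Spry4, changed by -0.86 and -0.71 on rDLL4, and Spry4 by -1.01 on rJAG1. The cytokine gene Il6 rose by 0.94 on rDLL4 and 1.54 ± 0.24 on rJAG1. Dlk1 changed by -1.50 ± 0.26 on rJAG1. Of the 6 fits that left out 1 library, Nrp1 and Il6 kept their calls on rDLL4 in 1, Spry2 in 3 and Spry4 in 4, while on rJAG1 Nrp1, Il6, Spry4 and Dlk1 kept theirs in all 6.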
